A study of Mus musculus with 3 samples.

How the data were processed

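Choices of tests, gene lists and alternatives were made before the data were examined, except where said otherwise. The labels describe total RNA libraries of the cytosolic fraction from 1 µg of RNA with a size range of 250 to 400. The 3 libraries are labelled as biological replicates but share 1 donor entry, that of the strain, and nothing in the labels says that they are separate animals or cultures, so their spread may be technical.

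Each library had a deposited gene table and a pair of deposited transcript tables. The gene table and the first transcript table gave expected counts and TPM per the file headers. The second transcript table gave estimated counts and TPM per the file headers, and its values were summed per gene. The aligner, the quantifiers and their versions are not given in the sources used here. Each gene table held 81881 rows, of which 55536 matched GENCODE release M21 by versioned ID, with no mouse gene row left without a match. The other rows were 26248 tRNA rows, 96 ERCC spike-in rows and 1 phiX row. These name no gene and were left out of the library sizes, and they held 0.350%, 0.169% and 0.168% of the expected counts of replicates 1, 2 and 3. The TPM of the authors were taken over all rows and were kept as deposited in the main values.

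Expected counts were rounded to whole numbers for TMM scaling and the coefficient of variation (edgeR 4.0.16) and for the DESeq2 1.42.0 size factors used as an alternative. Other steps used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Levels entered list comparisons as log2(TPM + 1). A list difference is the difference of list medians per library, with genes in both lists left out. Genes were permuted between the lists exactly or 100000 times, two-sided. List spread was set against 10000 random lists of the same size, matched on expression in 20 bins and centred on the mean of all detected genes. The chi-square test took genes with at least 10 counts in at least 1 library. When a library was left out, the chi-square test kept the TMM factors of all 3. The coefficient of variation was then computed with TMM factors estimated anew from the remaining libraries.

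The genes named are the 10 highest nuclear-encoded protein-coding genes, the 4 highest and the lowest member of each list, all members of the noncoding and Y-linked lists, the 10 protein-coding genes that departed most between libraries at a mean of at least 10 TPM, and the 5 most different genes in each direction between the quantifications. Other names were chosen after their values were seen, and some genes that these rules pick are not reported here. The list symbols Irg1 and Norad stand in the tables as Acod1 and 2900097C17Rik.

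The alternatives were a pseudocount of 0.1, members of at least 1 TPM, the second quantification, TMM-scaled CPM, list means and leaving out each library. Rescaled TPM, the mitochondrial share over protein-coding and long noncoding genes, the noncoding list without Rn7sk and Rmrp, random lists matched on length or GC content, and counts without replicate 3 or 1 were added after seeing the data. The lists of lysosomal, MHC, complement, splicing factor and NRF2 target genes were also chosen after the data were seen.

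In a self-test on simulated counts, the chi-square test recovered 58.0% of genes changed 1.25-fold in 1 library, 66.0% at 1.5-fold, 82.0% at 2-fold and 98.0% at 4-fold, of 50 each, and called 0.0696% of unchanged genes. A simulated coefficient of variation of 0.2 was estimated as 0.198. On the observed levels, the permutation test gave p under 0.05 for 4.5% of random list pairs. With normal deviations drawn independently for each gene, 6.0% of random lists without a shift fell outside the central 95%. Genes of a list can vary together between libraries, so that rate need not hold for the list spread.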

Results

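Cytosolic RNA was sequenced from C57BL/6J mouse bone-marrow-derived macrophages that had met Lipid A, the membrane-anchoring part of bacterial lipopolysaccharide, before. The cells had 100 ng/ml Lipid A for 12 h, a washout of 12 h and then 100 ng/ml Lipid A again for 120 min. The labels gave 1 group with 3 biological replicates, so no between-group test was possible and levels are described within this group. Values are TPM, a length-normalised measure of transcript abundance of the deposited gene table, mean ± SD (n = 3), unless a replicate is named. The libraries held 29376859, 64822118 and 37665844 expected counts in replicates 1, 2 and 3. Of 22028 protein-coding genes, 8612 reached 1 TPM in all 3 libraries, and 5211 reached 5 TPM. Other RNAs took most of the deposited TPM, which makes 1 TPM a stricter limit for protein-coding genes. On TPM rescaled over protein-coding and long noncoding genes 9963 reached 1 TPM, and in the second quantification 7410 did. At least 10 expected counts were held by 10956.

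The highest protein-coding transcripts were those of iron storage, chemotaxis, the cytoskeleton, antigen presentation and the lysosome. The ferritin genes Fth1 and Ftl1, which store iron, stood at 19170.1 ± 1683 and 7121 ± 340.0 TPM. Ccl5, a chemokine that attracts T cells, reached 6364 ± 527 TPM (mm10, ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518). Tmsb4x and Actb, genes of actin and its binding, stood at 4566 ± 745 and 3822 ± 365, and B2m and H2-K1, parts of MHC class I, at 3555 ± 576 and 2186 ± 147. Psap, a lysosomal activator of lipid breakdown, stood at 2796 ± 258. Lyz2, the macrophage lysozyme, stood at 2751 ± 2.59 TPM (ENSMUSG00000069516.8, chromosome 10, 117277331 to 117282321). This small SD depends on TPM being taken over all rows. Protein-coding genes held 32.5%, 26.5% and 27.1% of the TPM in replicates 1, 2 and 3. Relative to the protein-coding total, Lyz2 was thus lower in replicate 1 and not equally even. Saa3, an acute-phase protein, was uneven at 4958, 1846 and 6201 TPM in replicates 1, 2 and 3 (ENSMUSG00000040026.8, chromosome 7, 46711998 to 46715700).

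Protein-coding genes took 86.8% ± 2.11 of the expected counts but 28.7% ± 3.29 of the TPM. The genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, took 60.5% ± 2.7 of the TPM and 9.75% ± 1.48 of the counts. Cytosolic ribosomal protein genes took 1.46% ± 0.215 of the TPM and replication-dependent histone genes 0.0293% ± 0.00119. Mitochondrial-encoded genes took 0.156%, 0.125% and 0.398% of the TPM in replicates 1, 2 and 3, with a mean of 0.226% ± 0.149. Without replicate 3 that mean was 0.140%, and over protein-coding genes alone the shares were 0.473%, 0.4701% and 1.46%.

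Macrophage marker genes were abundant and those of other cell types were near 0. All 22 macrophage markers reached 1 TPM in every library and 17 reached 100 TPM, with a list median of 346 ± 37.5 TPM. Besides Lyz2 the highest were Ctsd, a lysosomal protease, at 2068 ± 92.2, Fcer1g, a signalling chain of Fc receptors, at 1429.7 ± 133, and Ctss, a protease of antigen processing, at 1092 ± 178. None of the mast cell and basophil, fibroblast and stromal, or erythroid markers reached 1 TPM in all libraries. Cd4, from the T and NK cell list, stood at 11.1 ± 1.54 TPM while Cd3e, a chain of the T cell receptor complex, stood at 0.0233 ± 0.0404. Of 12 neutrophil markers 3 reached 1 TPM in all libraries, S100a9 at 3.48 ± 1.38, S100a8 at 2.08 ± 0.572 and Mmp8 at 1.98 ± 0.273. The endothelial list had the highest median of the other types at 0.217 ± 0.0874 TPM, with Kdr at 4.21 ± 2.54 (2.77 without replicate 1) and Vwf at 2.497 ± 0.759.

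The macrophage list median lay 8.13 ± 0.15 log2 units above the endothelial one, higher in 3 of 3 libraries (exact permutation of genes between the lists, two-sided p = 1.41e-04, adjusted p = 4.23e-04 by Benjamini-Hochberg over 6 list differences). This p and those of the other list differences describe the lists and not a condition. The endothelial median lay near 0, so the size of the macrophage difference depended on the setting. It was 10.1 with a pseudocount of 0.1 and 7.03 in the second quantification.

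**Figure D1:**
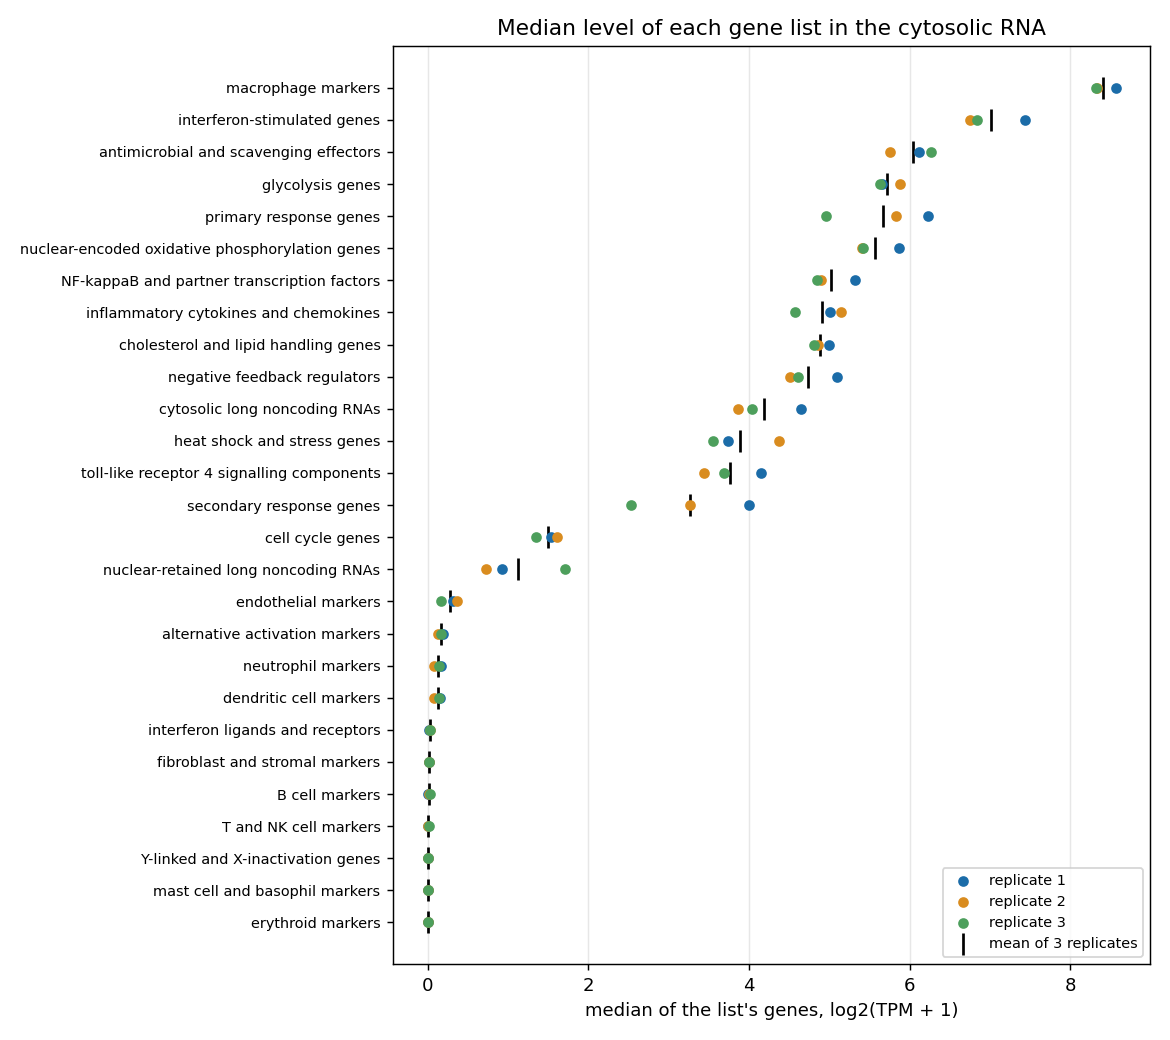
Median level of each gene list as log2(TPM + 1), with 1 point per replicate (n = 3). The macrophage list lies highest, at a median of 346 ± 37.5 TPM, and lists of other cell types lie near 0.

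Among long noncoding RNAs, several host genes of small nucleolar RNAs and Norad were present in every library, while Malat1, Neat1 and Gm26917 were uneven between libraries. Zfas1, Gas5 and Snhg8, host genes of small nucleolar RNAs, stood at 30.8 ± 14.99, 35.6 ± 7.75 and 10.5 ± 2.22 TPM, and Norad, listed as 2900097C17Rik and known to bind Pumilio proteins, at 51.7 ± 4.81. Snhg12, Epb41l4aos and Snhg1 stood at 5.83 ± 1.36, 5.69 ± 0.754 and 3.84 ± 0.903, and Dancr at 0.03, 0.09 and 0.24 in replicates 1, 2 and 3. Malat1, a nuclear speckle RNA, stood at 191, 133 and 952 TPM in replicates 1, 2 and 3 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), and at a mean of 162 without replicate 3. Neat1, the scaffold of paraspeckles, stood at 14.3, 10.9 and 55.6 and Gm26917, listed as nuclear-retained, at 112, 31.2 and 985, with means of 12.6 and 71.9 without replicate 3. Airn and Firre stood at 0.9, 0.65 and 1.66 and at 0.57, 0.3 and 2.27, Kcnq1ot1 at 0.02, 0.01 and 0.18, and Meg3 and Tsix at 0 TPM.

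The cytosolic list median lay 3.06 ± 0.70 log2 units above the nuclear-retained one, higher in 3 of 3 libraries, and the lists did not differ beyond chance (exact permutation of genes, two-sided p = 0.115, adjusted p = 0.172). The small structural RNAs Rn7sk and Rmrp had been placed in the cytosolic list before the data were seen, Rn7sk at 44769.9 ± 21816 TPM, whose 7SK RNA is largely nuclear, and Rmrp at 11599.8 ± 3317; without both the difference was 2.04. On TMM-scaled CPM (TMM is a scaling for library composition, CPM a library-scaled count) the difference was 0.81, with replicate 3 at -1.39.

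Primary response genes, the direct early targets of Lipid A signalling, stood above secondary ones, which mostly need new protein synthesis. Ccl4, Ccl3 and Ccl7, chemokines for monocytes and lymphocytes, stood at 1023 ± 369, 868 ± 260.3 and 525 ± 169.8 TPM, and Tnf, the inflammatory cytokine, at 505 ± 106 (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007). Of 36 primary genes, 32 reached 1 TPM in all libraries and 12 reached 100 TPM, and the list median was 53.6 ± 22.4. The lowest was Il23a, a cytokine subunit, at 0.17 ± 0.141, and at 0.095 without replicate 2. Of 23 secondary genes, 15 reached 1 TPM and 2 reached 100 TPM, with a median of 9.45 ± 5.14. Those at the top were Ccl5, Acod1, which makes itaconate, at 1369.5 ± 244 (ENSMUSG00000022126.6, chromosome 14, 103046977 to 103056573), Cd40, a costimulatory receptor, at 108 ± 28.2, and Ebi3, a cytokine subunit, at 95.8 ± 6.301. Il33 was lowest at 0.00667 ± 0.0115. Il12b and Il6, inflammatory cytokines, and Nos2, which makes nitric oxide, stood at 34.6 ± 15.8, 13.9 ± 5.89 and 10.8 ± 5.37, while Il1b stood at 272 ± 71.2; these 4 and Ifnb1 were singled out after their values were seen.

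The primary list median lay 2.41 ± 0.16 log2 units above the secondary one, higher in 3 of 3 libraries (permutation test, two-sided p = 0.0106, adjusted p = 0.0213; 0.00302 to 0.0472 over the alternative settings). No unstimulated or once-stimulated cells were analysed here, so these levels are not responses.

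**Figure D2:**
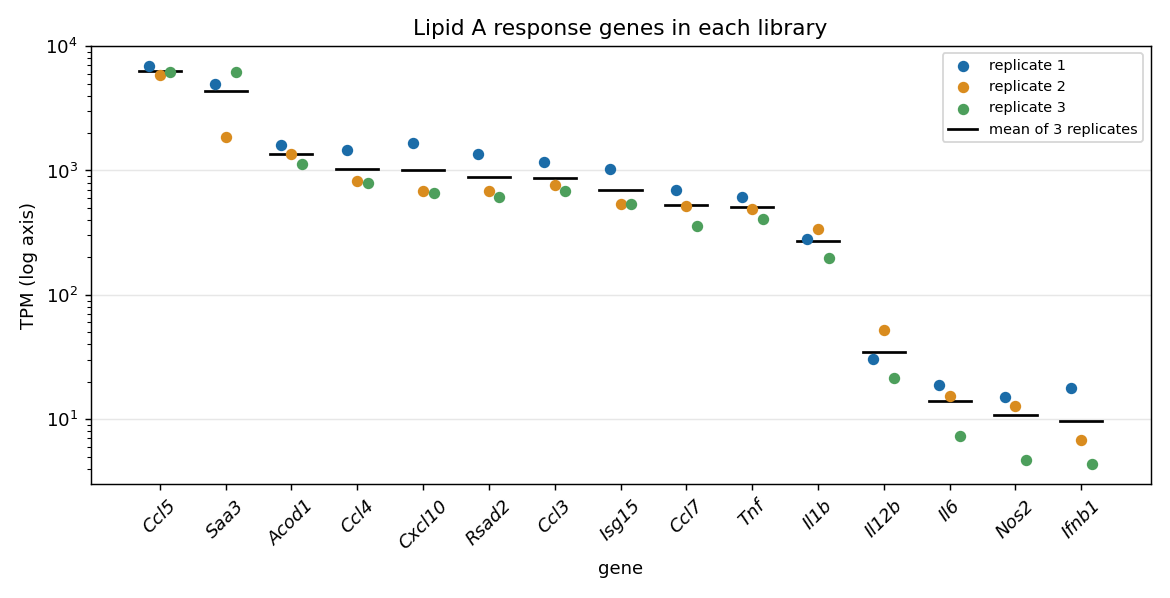
TPM on a log axis of Lipid A response genes in each replicate (points) with their mean (line, n = 3). Ccl5 was highest at 6364 ± 527 TPM and Ifnb1 stood at 17.8, 6.81 and 4.34 TPM in replicates 1, 2 and 3.

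Antimicrobial and scavenging genes and cytokine genes both held members of high level. Saa3 and Lyz2 led the first list, followed by Clec4e, a receptor for mycobacterial glycolipid, at 363 ± 81.3 TPM and Wfdc17, a secreted protease inhibitor, at 354 ± 53.2. Of 25 members 19 reached 1 TPM in all libraries and 7 reached 100 TPM, with a median of 65.6 ± 11.7. Ptx3, a secreted pattern recognition protein, was lowest at 0.0533 ± 0.0115. Of 33 cytokine and chemokine genes 26 reached 1 TPM and 10 reached 100 TPM, with a median of 29.4 ± 5.91. Cxcl10, a chemokine for activated T cells, stood at 1658, 680.0 and 664 TPM in replicates 1, 2 and 3 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), and Ccl17, a chemokine of alternative activation, at 0. The first median lay 1.13 ± 0.54 log2 units higher, in 3 of 3 libraries, and the lists did not differ beyond chance (permutation test, two-sided p = 0.365, adjusted p = 0.437). The difference was 0.34 with list means in place of medians and 1.89 on TMM-scaled CPM.

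Interferon-stimulated genes were expressed throughout. All 40 members reached 1 TPM in every library and 21 reached 100 TPM, with a median of 131 ± 36.2. Besides Cxcl10 the highest were Rsad2, an antiviral enzyme, at 886 ± 409, Isg15, a ubiquitin-like modifier, at 697 ± 283, and Irf7, a transcription factor of interferon genes, at 671 ± 226. Cxcl9, a chemokine of the interferon gamma response, was lowest at 3.95 ± 1.94. The receptor chains Ifnar2, Ifngr2, Ifngr1 and Ifnar1 stood at 59.5 ± 10.2, 35.1 ± 5.13, 33.8 ± 2.34 and 29.5 ± 0.8601. Ifnb1, which encodes interferon beta, stood at 17.8, 6.81 and 4.34 TPM in replicates 1, 2 and 3, and Ifnl3 at 0. The list median lay 3.75 ± 0.49 log2 units above that of the secondary response genes, higher in 3 of 3 libraries (permutation test, two-sided p = 1e-05, the smallest that 100000 permutations allow, adjusted p = 6.0e-05; 3.0e-05 to 0.000200 over the alternative settings).

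Components of Toll-like receptor 4 signalling, the route of Lipid A sensing, had a median of 12.8 ± 3.52 TPM. Cd14, which hands Lipid A to the receptor, stood at 228 ± 96.8, the kinases Mapkapk2 and Ikbke at 125 ± 28.2 and 70.05 ± 20.4, Irf5 at 65.0 ± 12.4 and Lbp, a serum carrier, at 0.453 ± 0.1701. Negative feedback regulators had a median of 26.1 ± 6.13, and 31 of 34 reached 1 TPM in all libraries. Nfkbia, the inhibitor of NF-kappaB, stood at 286 ± 65.97, Tnip3, which inhibits the same route, at 196 ± 19.7, Cd274, the checkpoint ligand PD-L1, at 188 ± 79.2, and Tnfaip3, a ubiquitin-editing enzyme, at 108 ± 44.6. Sigirr, an inhibitory receptor, was lowest at 0.253 ± 0.136. NF-kappaB and partner transcription factors had a median of 31.9 ± 6.204, with Klf6 at 183 ± 57.5 and Irf1 at 163 ± 56.2, and Fosl1 lowest at 0.0133 ± 0.0153.

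Glycolysis and nuclear-encoded oxidative phosphorylation genes had like levels. Gapdh, Aldoa, Pkm and Hk3, glycolytic enzymes, stood at 330.3 ± 37.1, 161 ± 14.5, 136 ± 9.996 and 104 ± 18.7 TPM, and Slc16a3, a lactate exporter, at 3.203 ± 0.903. Atp5b, of ATP synthase, stood at 226 ± 8.55, and Cox4i1, Cox5a and Cox6c, of cytochrome oxidase, at 168 ± 23.4, 141 ± 27.4 and 119 ± 3.07, with Ndufv1 of complex I lowest at 8.66 ± 0.577. All 17 and all 28 members reached 1 TPM in every library, with medians of 51.9 ± 5.13 and 47.2 ± 8.71. The difference of the medians was 0.16 ± 0.34 log2 units, positive in 2 of 3 libraries, and within chance (permutation test, two-sided p = 0.753, adjusted p = 0.753). It was 1.42 ± 0.08 on TMM-scaled CPM, which is not corrected for gene length (permutation test, adjusted p = 0.00348; 0.00348 to 0.998 over all settings), -0.29 with list means and -7.69e-04 without replicate 2.

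Cholesterol and lipid handling genes had a median of 28.6 ± 2.06 TPM. Fabp5, a fatty acid carrier, stood at 1074 ± 326, Apoe, a lipid exporter, at 850.2 ± 235, and Plin2, a lipid droplet coat protein, at 144 ± 41.8. Ch25h, which makes an oxysterol, was lowest at 1.9 ± 1.28, and at 1.22 without replicate 1. Cell cycle genes had a median of 1.83 ± 0.259, and 13 of 22 reached 1 TPM in all libraries. Pcna, a clamp of DNA replication, stood at 61.8 ± 8.09, Mki67 at 16.4 ± 3.52 and Plk1, a mitotic kinase, at 0.09 ± 0.0265. Of heat shock and stress genes, Hspa8 and Hspa5, chaperones, stood at 533 ± 47.1 and 181 ± 31.3, and Ddit3, a stress transcription factor, at 97.9 ± 34.8. Of 14 alternative activation markers 5 reached 1 TPM, with Tgm2 at 58.1 ± 20.99, Mrc1 at 15.9 ± 4.43 and Egr2 at 5.48 ± 3.07. Of the 28 lists, 11 had medians above the upper end of the central 95% of 10000 random lists of detected protein-coding genes, and 13 lay below its lower end. The random lists held detected genes only, so lists with many undetected members, such as the neutrophil list with 9 of 12 under 1 TPM on average, fell there by construction.

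The lowest pairwise correlation of libraries was Pearson r = 0.965 across 10128 genes, which are not independent replicates, on log2(TPM + 1). Of 14568 genes, 10433 differed between libraries beyond counting error (chi-square test of counts on 3 libraries, Benjamini-Hochberg at 0.05), and between 7213 and 8218 did when 1 library was left out. The biological coefficient of variation from edgeR was 0.338 as 1 common value over all genes. Fitted as a trend on expression, its median over genes was 0.210. Without replicates 1, 2 and 3 in turn that median was 0.226, 0.205 and 0.188. The common value was 0.418, 0.307 and 0.216 without replicates 1, 2 and 3 in turn. Protein-coding genes that departed most from the other libraries included Cebpb, an inflammatory transcription factor, at 56.5, 10.98 and 14.98 TPM in replicates 1, 2 and 3, Slc13a3, a dicarboxylate transporter, at 16.9, 61.1 and 44.4, and Cxcl1, a neutrophil chemokine, at 18.6, 20.9 and 5.21. Tgtp1 and Ifit1bl1, interferon-induced genes, stood at 31.02, 4.82 and 7.02 and at 164, 36.7 and 37.7. Mmp13, a collagenase, stood at 18.5, 11.6 and 4.63, and mt-Atp8 and mt-Nd6, mitochondrial-encoded genes, at 457, 91.2 and 1319 and at 78.6, 80.1 and 265. Gm20721 and Gm49369, predicted genes, stood at 2.36, 47.9 and 15.5 and at 51.6, 358 and 559.

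Some gene lists differed between the libraries by more than matched random lists. Interferon-stimulated genes lay 0.61 log2 units higher in replicate 1 than the mean of the other libraries (SD over members 0.36), and 39 of 40 members were highest there. Cytokine and primary response genes lay at -0.69 and -0.55 in replicate 3, with SDs over members of 0.38 and 0.42, and 0 of 28 and 1 of 34 members were highest there. Nuclear-retained long noncoding RNAs lay 2.29 higher in replicate 3 (SD 1.26), in 6 of 6 detected members, and mitochondrial-encoded protein-coding genes 1.40 higher (SD 0.45), in 12 of 13. Heat shock and stress genes lay 0.44 higher in replicate 2 (SD 0.47), in 12 of 17, and at -0.42 in replicate 3. Of the fixed lists scored for spread, 8 lay above the upper end of the central 95% of random lists matched on expression, and 4 did without replicate 3. Not all of the 28 fixed lists were scored. Several of the 8 lists share members, so they are not separate results.

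**Figure D3:**
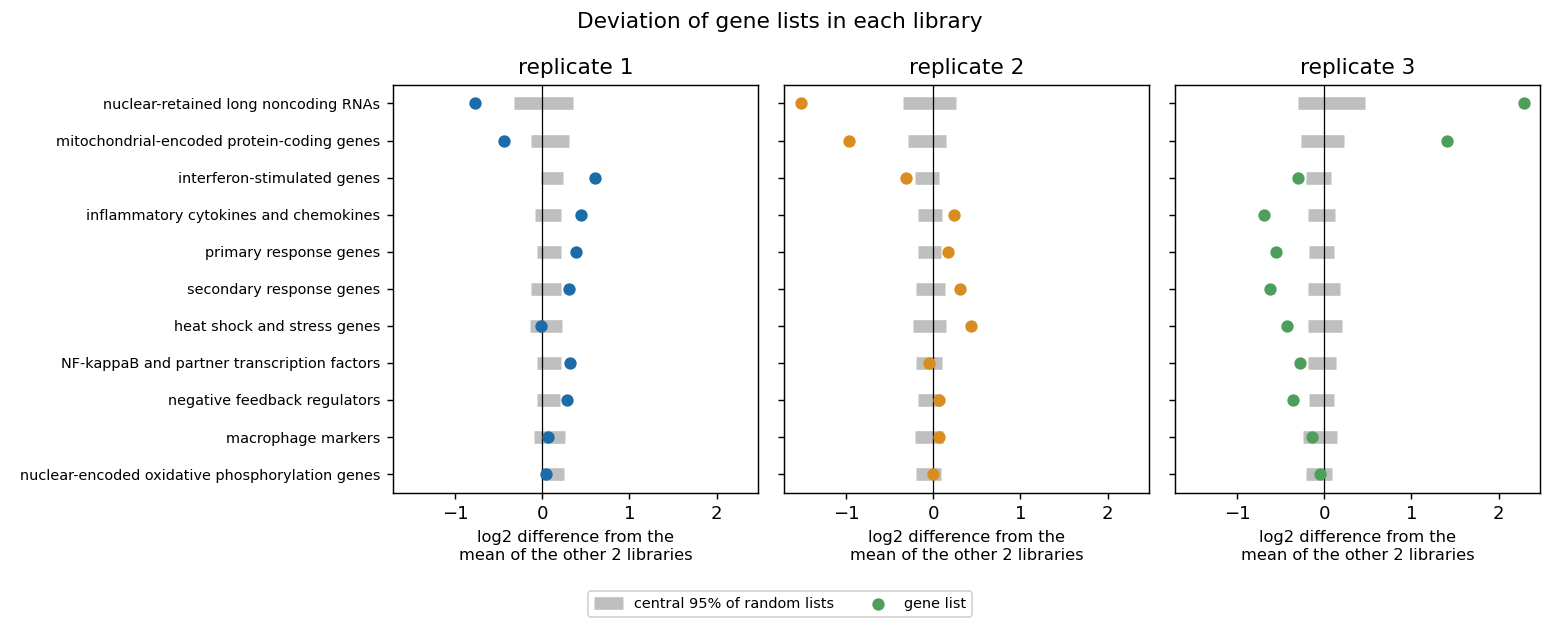
Log2 difference of each list from the mean of the other 2 libraries (points), with the central 95% of matched random lists (bars). Nuclear-retained RNAs in replicate 3 (2.29) and interferon-stimulated genes in replicate 1 (0.61) lie outside it.

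Of 12 response genes examined, 8 had 1 transcript with over 50% of the gene's TPM. Those of Myd88, an adaptor of the receptor, and Zc3h12a, an RNase, took 99.5% ± 0.459 and 97.2% ± 0.283, and that of Cd274, with 1 annotated transcript, was fixed at 100%. For Il1rn, the interleukin 1 receptor antagonist, Il1rn-201 took 76.9% ± 1.26, and for Nfkbiz, a nuclear NF-kappaB cofactor, Nfkbiz-204 took 72.3% ± 3.64. Irak2-201, Csf1-201 and Traf1-201 took 76.5% ± 7.83, 66.96% ± 2.29 and 54.4% ± 2.34. Irf7-201 and Il15-202 took 47.3% ± 1.903 and 46.8% ± 2.15. Both quantifications gave the same leading transcript in 10 of 12 genes. For Nfkb2, an NF-kappaB subunit, the leader was Nfkb2-201 in the first at 46.8% ± 5.07 and Nfkb2-202 in the second at 52.2% ± 0.785, and in replicate 1 of the first Nfkb2-202 led with 45.3% against 42.1%.

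The second deposited quantification placed most protein-coding genes lower, with a median log2 ratio to the first of -0.97 over 3747 genes. After both were rescaled over protein-coding and long noncoding genes, the median was -0.00373 over 7220 genes. Then 30 genes lay over 2-fold higher in all 3 libraries and 25 lay under 0.5 of the first value. Rps12 and Rpl12, ribosomal protein genes, stood at 327 ± 77.4 and 85.1 ± 12.9 TPM in the first and 7.93 and 1.51 in the second, and Atp5g2 of ATP synthase at 37.6 ± 10.5 and 1.89. CAAA01147332.1 and B430305J03Rik stood at 21.9 ± 6.13 and 22.03 ± 4.65 in the first and 0 and 1.19 in the second. Higher in the second were Rps12-ps3 and Rpl10-ps3, ribosomal protein pseudogene relatives, at 171 and 131 against 10.4 ± 3.47 and 19.01 ± 1.21. So were mt-Atp6 at 133 against 27.8 ± 12.4, and Gm11027 and Gm17374 at 91.7 and 122 against 0.

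The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all libraries, which allows up to 0.102, 0.0464 and 0.0798 CPM in replicates 1, 2 and 3 by counting error alone. Xist, the RNA that coats the inactive X, stood at 2.23, 0.67 and 19.7 TPM (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254), with a mean of 1.45 without replicate 3. The labels gave no sex.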

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

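The tests of depth and of the share of counts taken by a few genes and the Ifnb1 test were chosen after the result was seen.

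A signal in data outside the gene values was the phiX row, a sequencing control genome, with 102945, 109710 and 63089 expected counts in replicates 1, 2 and 3.

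Replicate 3 held more nuclear-retained noncoding RNA, 2.29 log2 units over the other libraries in 6 of 6 members. That library ranked 2 of 3 in expected counts, so the excess did not follow the order of sequencing depth. TMM scaling kept 0.969 of the deviation not centred on other genes. With TMM factors of 0.976, 0.983 and 1.04 in replicates 1, 2 and 3 it could change little, so this outcome was fixed. It shows only that composition, as TMM measures it, differed little between libraries. The centred deviation stayed at percentile 100 among GC-matched lists, whose central range in replicate 3 was -0.277 to 0.566. Lists of other genes of like expression and GC content thus did not rise as much. The median GC content of the 9 listed members was 46.5%, near the 49.2% of detected genes. Matching on GC content could therefore change little, and the test leaves GC content undecided as a source of the excess. Carry-over of nuclear RNA stays open and could explain it: the retained-intron share of replicate 3 was 1.15 times that of the higher other library, though replicate 2 exceeded replicate 1 by 1.16 times, and in the second quantification these ratios were 1.32 and 1.04. Other nuclear RNA was also higher in replicate 3, with snRNA genes at 0.418%, 0.4196% and 0.881%, snoRNA genes at 0.116%, 0.0395% and 0.331% and scaRNA genes at 0.0213%, 0.0213% and 0.0731% of the TPM in replicates 1, 2 and 3, and no biological explanation was tested. Mitochondrial-encoded protein-coding genes lay 1.40 log2 units higher there too, in 12 of 13 members, so the rise was not confined to nuclear RNA.

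Replicate 1 held more interferon-stimulated RNA, 0.61 log2 units over the other libraries in 39 of 40 members. TMM scaling left 1.096 times the deviation not centred on other genes. The TMM factors differed too little to take it away, so this shows only that composition, as TMM measures it, differed little. The centred deviation stayed at percentile 100 among length-matched lists, which argues against gene length. It stayed at 100 among GC-matched lists too, so lists of other genes of like GC content did not rise as much. The list's median GC content of 47.5% lay near the 49.2% of detected genes. Matching on GC content could therefore change little, and the test leaves GC content undecided. A higher interferon beta transcript level in replicate 1 could go with the excess as a hypothesis: Ifnb1 TPM was 2.61 times that of the higher other library. Other response lists were higher in replicate 1 mainly where replicate 3 was low: without replicate 3, cytokines lay 0.14 and primary response genes 0.15 above replicate 2, inside the range of random lists, NF-kappaB and partner factors 0.25, above it, and interferon-stimulated genes 0.61. Ifnb1 was found and tested on the same data, and a difference in culture or timing stays untested.

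Small structural RNAs took 69.7% ± 3.19 of the TPM but 11.5% ± 1.98 of the counts. With annotated in place of effective lengths the share was 42.1%, 51.2% and 48.1% in replicates 1, 2 and 3, at most 0.707 of the deposited share, so short effective lengths could explain part of it and how far stays open. In the first quantification miRNA genes took 0.00407% ± 0.00374 of the TPM and processed pseudogenes 0.203% ± 0.0167. The second quantification gave the structural RNAs 27.8% ± 5.95 of its TPM, miRNA genes 31.3% ± 2.57 and processed pseudogenes 26.2% ± 6.68. The high miRNA and pseudogene shares of TPM were thus seen in the second quantification only. Of its counts structural RNAs, miRNA genes and processed pseudogenes took 10.2% ± 1.95, 2.01% ± 0.502 and 5.65% ± 1.56. The count share of the structural RNAs was thus near the 11.5% of the first quantification. Sequence shared with the signal recognition particle RNA genes did not account for the short genes that lead it, since 0 of their 31-base words occur in Rn7s1 or Rn7s2.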

How the results depend on the processing

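Of the alternatives to the main values, 86 values of the comparisons stayed the same, that is in direction and side of the threshold for list differences, within 1 SD for shares and correlations and within 1.5 times for counts, and among single lists and genes 744 moved by less than 1 SD between libraries and 422 by more. Leaving out 1 of 3 libraries cannot move a mean by 1 SD, so those values say nothing on its stability. They include all 163 named genes without each replicate, so the 744 overstates stability. On TMM-scaled CPM 116 named genes moved and 47 stayed, and on rescaled TPM 146 moved and 17 stayed. In the second quantification 115 moved and 48 stayed. No paired analysis was possible because the labels give 1 group. Depth limits genes near 0.102, 0.0464 and 0.0798 CPM in replicates 1, 2 and 3. The macrophage difference had no value with members of at least 1 TPM, since the highest other list then kept a single gene, Cd4. The glycolysis minus oxidative phosphorylation difference became stronger on TMM-scaled CPM at 1.42 (permutation adjusted p = 0.00348), and reversed with list means at -0.29 and without replicate 2 at -0.000769; it ranged from -0.000769 to 0.34 with 1 library left out. Detected protein-coding genes moved to 5211 at 5 TPM. The lowest correlation moved to 0.934 with a pseudocount of 0.1, 0.989 over all genes listed and 0.946 in the second quantification, and ranged from 0.965 to 0.972 with 1 library left out. The mitochondrial-encoded share moved to 0.801% over protein-coding genes and 0.780% over protein-coding and long noncoding genes. The number of lists with excess spread ranged from 4 to 9 with 1 library left out, and was 4 without replicate 3. Fewer genes pass a higher TPM threshold and CPM is not divided by gene length, by construction; the cause of the other shifts was not tested.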

Other observations

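All lists in this part were chosen after the data were seen. Lysosomal genes were among the most abundant, with 14 of 20 at 100 TPM or more in all libraries and a median of 219.9 ± 19.3 TPM (n = 3). Ctsb, a protease, stood at 1665 ± 183, and Lamp1, a membrane protein, at 518 ± 99.2. Complement genes had a median of 177 ± 18.9, with C1qb and C1qc, which start the classical pathway, at 912 ± 69.7 and 676 ± 96.0 and C3, the central component, at 114 ± 34.4. MHC class I genes had a median of 177 ± 29.4, with H2-D1 at 1492 ± 82.2, and MHC class II genes 37.9 ± 6.45, with Cd74, the invariant chain, at 248 ± 49.5 and H2-Aa at 58.6 ± 11.7.

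Targets of NRF2, a regulator of the oxidative stress response, lay 0.80 log2 units higher in replicate 2 than the mean of the other libraries (SD over members 0.32), in 14 of 14 members. Txnrd1, a thioredoxin reductase, stood at 41.8, 64.7 and 36.0 TPM in replicates 1, 2 and 3, and Srxn1, a sulfiredoxin, at 14.3, 25.3 and 12.5. Splicing factor genes lay 0.36 higher in replicate 3, in 15 of 20 members. The heat shock and stress list, fixed before, shares several of these genes and was also higher in replicate 2. Both added lists were drawn up partly because members had been seen to stand out, so they are not independent evidence.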
